A study of Gallus gallus with 26 samples.

How the data were processed

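RNA was extracted from frozen complexus muscle of broiler chickens, per the labels' protocols, and 26 MARS-Seq libraries of 5 days were analysed, with 6, 6, 5, 5 and 4 libraries at E15, E17, E19, E20 and E21. The labels give a single batch for all samples. The submitters' processing notes name STAR 2.7.10a, HTSeq 2.0.2 and DESeq2, without their settings. The genome build, the annotation and the treatment of molecular identifiers and of strand are not given in the sources used here. Reads shared between near-identical or overlapping genes can therefore not be told apart in these values.

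MARS-Seq is named by the series description, whereas the labels' protocol leaves the library preparation unfilled, and whether a count is a read or a unique molecule is not given in the sources used here. The authors deposited a table of whole-number counts per gene and library, per the file headers raw counts, with one column for each of the 26 libraries. Beside them the authors deposited a normalised signal, which the file headers call normalised counts. It was the raw count divided by one size factor per library, within a relative difference of at most 0.00463, and served only to check the columns. The deposited table further holds the authors' log2 fold changes for 5 comparisons, and the p-values adjusted by the authors for the same comparisons. Per the file headers it also gives the authors' calls and 2 sets of cluster numbers, 1 attributed to DESeq2 and 1 to maSigPro. The deposited thresholds for a call were an adjusted p of 0.05, an absolute log2 fold change of 1 and a threshold of 30 on the maximum count of a gene. The table lists 8758 genes, and the lowest maximum count of a listed gene was 6, so genes below that level are not analysed here. The 917 genes of the clusters attributed to DESeq2 were the 917 genes that the authors had called in at least 1 of the 4 comparisons of successive days.

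Genes are given as versioned Ensembl identifiers, which the files do not pair with names. A table of 25635 RefSeq genes was searched for them, and 0 of the 8758 identifiers matched. Tests of gene lists, markers of cell types, W-linked genes as a covariate, and the exclusion of haemoglobin and mitochondrial genes had been fixed before the data were examined but need names, and they are not analysed here. The rule for named genes took those with the largest rise or fall among genes with an adjusted p under 0.05, a mean of at least 10 CPM on the higher day and libraries of the 2 days that do not overlap. Its further condition of a gene symbol could not be applied, and the first 2 genes in each direction from E21 against E15 are named.

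Library totals ranged from 580768 to 2208872 counts. A count of 0 in a single library allows up to 5.17 CPM in the shallowest library and 1.36 CPM in the deepest, taking 3 counts as the limit. Such floors and the 95% intervals cover counting error only. Within each day, 56 pairs of replicates were compared by a chi-square of their counts over genes. The statistic per degree of freedom lay between 3.1 and 14.6, no pair held identical values, and every library was counted as 1 sample.

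Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. TMM factors were used, and filterByExpr by day with a minimum count of 10 and a minimum total of 15 kept 5901 genes that held 99.23% of the counts. All 26 libraries entered 1 fit with day as the only term, so that the days shared the estimate of the spread, with a common biological coefficient of variation of 19.2%. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were counted, with a second count for those that also differed at least 2-fold. The comparisons were E17 against E15, E19 against E17, E20 against E19, E21 against E20, E21 against E15, and any difference between the 5 days. The comparison after against before hatching was added once the deposited table showed that the authors had made it. It sets the mean of the E20 and E21 coefficients against that of E15, E17 and E19.

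Levels of single genes are CPM normalised with the TMM factors. The SE given with a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It was not estimated separately by the fit. Cluster means were computed per library from log2 CPM, normalised with the same factors, with a prior count of 2, centred on the mean of the 5 day means. Differences in cluster means and in the share of the 20 genes with the most counts were tested with exact two-sided permutation tests of the library values. The TMM factors lay between 0.749 and 0.837 at E19 and between 1.22 and 1.33 at E21, which offset the changing share of the most abundant genes. Without them the median log2 fold change of all genes moved by -0.24 from E15 to E17, by -0.25 from E17 to E19, by 0.34 from E19 to E20 and by 0.37 from E20 to E21. Changes are therefore reported relative to the bulk of the genes. The median change of clusters 1 to 4 and of the 20 most abundant genes kept its sign under total-count scaling in every comparison of days, but that of cluster 2 went from 0.37 to 0.11 from E15 to E17 (65 genes higher and 2 lower, then 40 and 17) and from 0.28 to 0.03 from E17 to E19 (47 and 2, then 26 and 15). That of the 20 genes went from 0.60 to 0.36 and from 0.36 to 0.12 in these steps, from -0.60 to -0.26 from E19 to E20 and from -0.91 to -0.54 from E20 to E21. From E15 to E17 that of cluster 4 went from 0.41 to 0.16. From E19 to E20 that of cluster 1 went from -0.69 to -0.36, that of cluster 3 from 0.39 to 0.72 and that of cluster 4 from 0.04 to 0.39. From E20 to E21 that of cluster 1 went from -0.65 to -0.29, that of cluster 2 from -0.76 to -0.39, that of cluster 3 from 0.38 to 0.73, that of cluster 4 from -0.86 to -0.48 and that of cluster 5 from 0.22 to 0.58. From E15 to E21 that of cluster 3 went from -0.46 to -0.23 and that of the 20 genes from -0.51 to -0.29. That of cluster 5 turned from 0.01 to -0.23 from E15 to E17 and from 0.07 to -0.19 from E17 to E19.

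The tests were checked on simulated counts drawn from the means, library sizes and dispersions of the 5901 genes, with 200 genes changed. For E20 against E19, edgeR recovered 60% of the genes changed 2-fold and 89% of those changed 4-fold, with 3 false calls. For E17 against E15 it recovered 82% and 99%, with 8 false calls. For E19 against E17 the values were 60% and 93% with 10 false calls, for E21 against E20 57% and 92% with 2, and for E21 against E15 65% and 94% with 8.

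The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, a filter of at least 5 CPM in at least 4 libraries, fits of only the 2 days compared, the replicate number as a block, exclusion of the 20 most abundant genes, limma-voom with quality weights (limma 3.58.1), and each library left out in turn. Total-count scaling, a covariate made from genes that are present in only part of the libraries, and a fit of 2 groups without day were added after seeing the data, as were the tests of the share of the 20 most abundant genes and of the clusters. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.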

Results

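The complexus is the neck muscle with which the chick breaks the shell at hatching. Its transcriptome was measured in broiler chickens (Gallus gallus) on 5 days around hatching by MARS-Seq, per the series description. The 26 libraries fell into 6 of embryonic day 15 (E15), 6 of E17, 5 of E19, 5 of E20 and 4 of E21. The sample labels name the last 2 groups by embryonic day, whereas the series description speaks of hatch and chick placement. The libraries held from 580768 counts (E19 replicate 5) to 2208872 counts (E15 replicate 3), with between 7329 and 8593 genes counted per library. The deposited table lists 8758 genes by Ensembl identifier without pairing them with names. The account therefore rests on groups of genes, such as the most abundant ones and the clusters that the authors deposited, and on 4 single identifiers. The labels do not say whether the libraries came from separate birds, so the p-values measure only the spread between these samples.

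Day set the order of the libraries. Each of the 26 libraries had its highest correlation with a library of its own day, and the median correlation with the other libraries of that day lay between 0.926 and 0.969 across genes, which are not independent replicates. The first principal component held 42.5% of the variance and ran in order of age, with means of -37.2 at E15, -24.8 at E17, -1.6 at E19, 37.3 at E20 and 48.3 at E21. The ranges of the days did not overlap on it. On the second component, with 12.8% of the variance, E19 stood at one end with a mean of -30.7, and E15 and E21 stood at the other with means of 18.5 and 19.2.

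The first question was which genes changed at all over the period. Of 5901 genes tested, 4195 (71.1%) differed between any of the 5 days at an adjusted p under 0.05 in the quasi-likelihood F test of edgeR with Benjamini-Hochberg adjustment. Of these, 1274 (30.4%) had their highest mean at E15 and 1193 (28.4%) at E21. A further 699 (16.7%) were highest at E19, 567 at E20 and 462 at E17. The day means of 272 genes rose at every step and those of 372 fell at every step, while 3551 (84.6%) did neither. Only the sign of each difference between day means was counted, so a small reversal within the spread also counts as neither. With library totals as the scale, 5052 genes differed between any of the 5 days. The days of the highest mean and the steps were not recounted on that scale.

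Gene expression in the muscle became more concentrated up to E19 and then less so. The 20 genes with the most counts over all libraries took 30.6% ± 1.39 of the counts at E15 (SD, n = 6), 38.5% ± 1.68 at E17 (SD, n = 6) and 43.1% ± 1.2 at E19 (SD, n = 5). Their share was 35% ± 1.16 at E20 (SD, n = 5) and 22.1% ± 0.6 at E21 (SD, n = 4). In exact two-sided permutation tests, the share rose by 7.82 points from E15 to E17 (p = 0.00216) and by 4.61 points from E17 to E19 (p = 0.00216). It fell by 8.12 points from E19 to E20 (exact p = 0.00794), by 12.8 points from E20 to E21 (exact p = 0.00794), and over the whole period from E15 to E21 it fell by 8.5 points (exact p = 0.00476). After Benjamini-Hochberg adjustment over these 5 exact tests the p-values lay between 0.0054 and 0.00794. Without the gene with the most counts, the differences from day to day were 4.9, 3.73, -5.75 and -7.01 points (exact permutation p = 0.00216, 0.00433, 0.00794 and 0.00794), and that from E15 to E21 was -4.13 points (exact p = 0.00476). The tests of this share and of the cluster means were chosen after the data had been seen. The closest libraries of successive days were 32.9% at E15 against 35.7% at E17, and 40.2% at E17 against 41.9% at E19.

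**Figure D1:**
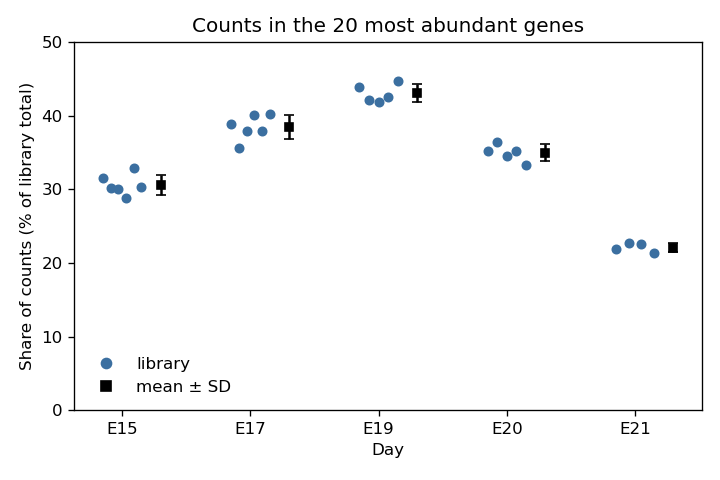
Share of each library's counts taken by the 20 genes with the most counts over all 26 libraries, in percent, by day. Circles are libraries and squares with bars are means ± SD over 6, 6, 5, 5 and 4 libraries. The share was 43.1% at E19 and 22.1% at E21.

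The authors' deposited table assigns 917 genes to 5 clusters, and 903 of these genes were tested here. The 917 genes are those that the authors had called between successive days in these same libraries, so the clusters describe the course of expression and are not independent evidence of its direction. The counts of cluster genes and the exact permutation p-values of cluster means given below follow in part from that selection. They describe the clusters and are not tests of whether such changes exist. Levels are given as mean log2 CPM, counts scaled by library totals and TMM factors, relative to the mean over the 5 days. Cluster 1 (199 genes tested) fell throughout, from 1.31 ± 0.13 at E15 (SD, n = 6) to -1.24 ± 0.08 at E21 (SD, n = 4). Cluster 2 (171 genes) rose to 0.84 ± 0.06 at E19 (SD, n = 5) and fell to -1.19 ± 0.12 at E21 (SD, n = 4). The median change of its genes was 0.37 from E15 to E17 and 0.28 from E17 to E19 with TMM factors, against 0.11 and 0.03 with library totals as the scale. Cluster 3 (81 genes) stood at 0.92 ± 0.17 at E15 (SD, n = 6), reached its lowest level of -0.62 ± 0.08 at E19 (SD, n = 5) and came back to 0.13 ± 0.05 at E21 (SD, n = 4). Cluster 4 (161 genes) rose from -1.02 ± 0.04 at E15 (SD, n = 6) to 0.83 ± 0.17 at E20 (SD, n = 5) and returned to 0.04 ± 0.09 at E21 (SD, n = 4). Cluster 5 (291 genes) lay between -0.73 and -0.64 up to E19 and then stood at 0.89 ± 0.13 at E20 (SD, n = 5) and 1.18 ± 0.08 at E21 (SD, n = 4). Its level course up to E19 depended on the scaling. The median change of its genes was 0.01 from E15 to E17 and 0.07 from E17 to E19 with TMM factors, against -0.23 and -0.19 with library totals.

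**Figure D2:**
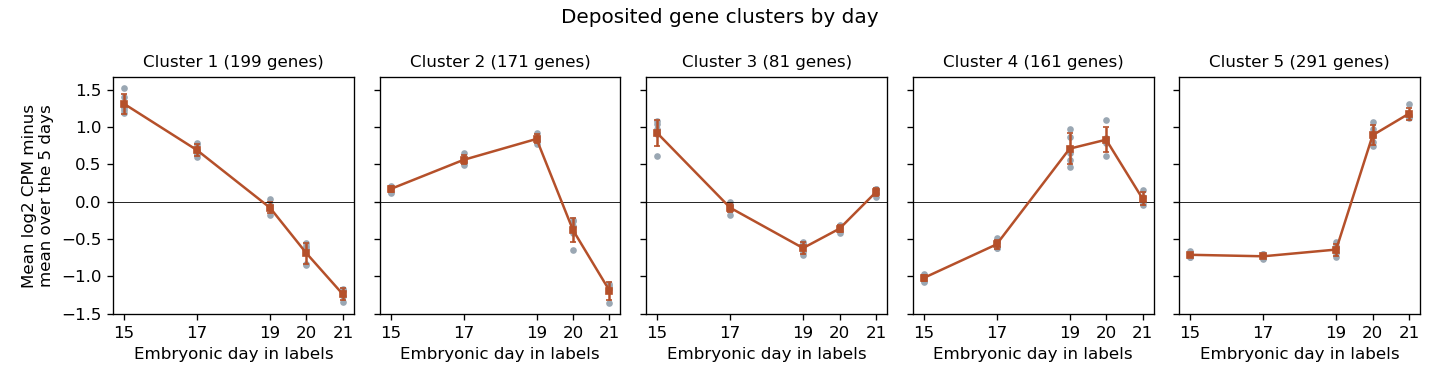
Mean log2 CPM of the 5 deposited gene clusters relative to the mean over the 5 days, against the embryonic day in the labels. Circles are libraries, squares with bars are means ± SD over 6, 6, 5, 5 and 4 libraries, and lines join the days. Cluster 5 stood at -0.64 at E19 and 0.89 at E20, whereas cluster 1 fell from 1.31 to -1.24.

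Between E15 and E17 most of the abundant genes of the muscle rose, and part of the genes of clusters 1 and 3 fell. Of the 20 most abundant genes, 13 rose and 1 fell, with a median log2 fold change of 0.60. With library totals as the scale, 12 rose and 3 fell, with a median of 0.36. In cluster 1, 2 of 199 genes rose, 85 did not pass the test and all others fell, and the cluster mean dropped by 0.62 on the log2 scale (exact two-sided permutation p = 0.00216, 0.00675 after Benjamini-Hochberg adjustment over 5 clusters and 5 comparisons). In cluster 3, 39 of 81 genes fell, 42 did not pass the test and none rose, and its mean dropped by 1.00 (exact permutation p = 0.00216). Gene ENSGALG00000042685.1 had 99.4 ± 61.4 normalised CPM at E15 (SD, n = 6), with 21.3 to 186 in single libraries, and no count in any library of the later days. Over the 6 E17 libraries a level of 0 stands for at least 272-fold less than the E15 mean, taking 3 counts over the group as the floor. Gene ENSGALG00000028843.2 had 55.7 ± 47.2 normalised CPM at E15 (SD, n = 6) from 388 counts, with 3.99 to 129 in single libraries, 1 count at E17 and none afterwards. The ratio of E15 to E17 was 370, with an exact 95% Poisson interval from 66 to 14600 that covers counting error only.

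Over all genes tested, 1047 differed between E17 and E15 at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 536 higher and 511 lower at E17. At least 2-fold differences were found for 62 of the higher and 139 of the lower genes. Without E15 replicate 4, 751 genes differed, 416 higher and 335 lower, and without E15 replicate 3, 826 differed, 435 higher and 391 lower. The counts in both directions thus depended in part on single libraries. In a fit of only the E15 and E17 libraries, 1301 genes differed, 671 higher and 630 lower. The authors' deposited table called 167 genes (57 higher, 110 lower), of which 159 were tested and 159 also differed here, 152 of them at least 2-fold. The authors' calls, unlike the count of genes that differed here, also need an absolute log2 fold change of 1 and apply a threshold of 30 to the maximum count of a gene. Scaled by library totals without TMM factors, 1679 genes differed, 185 higher and 1494 lower, so the balance of higher and lower genes depended on the scaling.

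From E17 to E19 cluster 4 rose. Of its 161 genes, 138 rose and none fell, and the cluster mean rose by 1.27 on the log2 scale (exact two-sided permutation p = 0.00216, adjusted 0.00675). Cluster 1 continued its fall, with 96 of 199 genes lower at E19 and a mean that dropped by 0.77 (exact permutation p = 0.00216). In cluster 3, 29 of 81 genes fell. Of the 20 most abundant genes, 11 rose and none fell, against 8 and 4 with library totals as the scale. Gene ENSGALG00000017316.4 first reached appreciable levels here, with 1.21 ± 0.811 normalised CPM at E17 (SD, n = 6) and 22.1 ± 21.3 at E19 (SD, n = 5), a log2 fold change of 4.04 (SE 0.62, adjusted p = 2.21e-05, edgeR with Benjamini-Hochberg). The E19 libraries ranged from 0 to 53.8.

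In all, 1017 genes differed between E19 and E17 (edgeR, adjusted p under 0.05), 583 higher and 434 lower at E19. Differences of at least 2-fold were found for 225 of the higher and 151 of the lower genes. The authors' deposited table, with its stricter thresholds, called 248 genes (147 higher, 101 lower), and 244 of the 245 tested also differed here, 243 of them at least 2-fold. With library totals as the scale, 1572 genes differed, 324 higher and 1248 lower.

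From E19 to E20 clusters 5 and 2 moved in opposite directions. In cluster 5, 268 of 291 genes were higher at E20 and none lower, and its mean rose by 1.53 on the log2 scale (exact two-sided permutation p = 0.00794, the smallest p that 5 against 5 libraries allow). Cluster 2 went the other way, with 150 of 171 genes lower, none higher and a mean that dropped by 1.22 (exact permutation p = 0.00794). In cluster 4, 33 genes were higher and 22 lower, and the difference in means of 0.13 was within the spread between libraries (exact permutation p = 0.317). With library totals as the scale, 56 genes of cluster 4 were higher and 10 lower. Of the 20 most abundant genes, 14 fell and 3 rose. Gene ENSGALG00000014616.5 had at most 5.35 ± 8.02 normalised CPM in the mean of any day up to E19 (SD, n = 5), where 1 library held 17 of the 22 counts. At E20 it stood at 742 ± 708 (SD, n = 5), between 120 and 1880 in single libraries. The log2 fold change was 6.90 (SE 0.63, adjusted p = 5.66e-10, edgeR with Benjamini-Hochberg).

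Across the transcriptome, 1621 genes (27.5%) differed between E20 and E19 (edgeR, adjusted p under 0.05), 820 higher and 801 lower at E20. At least 2-fold differences were found for 411 of the higher and 287 of the lower genes. The fit shares the spread between all days, and the libraries of E19 and E20 varied more than those of E15 and E17. In a fit of only the E19 and E20 libraries, 1251 genes differed, 620 higher and 631 lower. The authors' deposited table, with its stricter thresholds, called 468 genes (283 higher, 185 lower), and 466 of the 466 tested differed here, 451 of them at least 2-fold. With library totals as the scale, 2089 genes differed, 1761 higher and 328 lower.

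Between E20 and E21 most of the abundant genes fell, as did 89 of 171 genes of cluster 2 and 84 of 161 of cluster 4. Of the 20 most abundant genes, 15 fell, 9 of them at least 2-fold, and 1 rose. In cluster 4, 3 genes rose and 74 did not pass the test, and the mean dropped by 0.79 on the log2 scale (exact two-sided permutation p = 0.00794, adjusted 0.00945). In cluster 2, none rose and 82 did not pass the test. The mean of cluster 5 rose by 0.29 (exact permutation p = 0.0159, adjusted 0.0181), with 65 genes higher and 7 lower. These counts depended on the scaling: with library totals, 55 genes of cluster 4 fell and 11 rose, 70 of cluster 2 fell and 14 rose, and 145 of cluster 5 were higher and 2 lower. The sizes moved too: the median log2 fold change of cluster 5 went from 0.22 to 0.58, that of cluster 4 from -0.86 to -0.48, that of cluster 2 from -0.76 to -0.39 and that of the 20 most abundant genes from -0.91 to -0.54. In cluster 3, 25 of 81 genes rose. ENSGALG00000017316.4 had 194 ± 56.5 normalised CPM at E20 (SD, n = 5) and 193 ± 55.3 at E21 (SD, n = 4), a log2 fold change of -0.01 (SE 0.29, adjusted p = 0.994 in edgeR).

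Here 846 genes differed between E21 and E20 (edgeR, adjusted p under 0.05), 339 higher and 507 lower at E21. At least 2-fold differences were found for 80 of the higher and 270 of the lower genes. Without E21 replicate 1, 578 genes differed, 224 higher and 354 lower. The authors' deposited table, with its stricter thresholds, called 246 genes (73 higher, 173 lower), and 242 of the 244 tested differed here, 241 of them at least 2-fold. With library totals as the scale, 1947 genes differed, 1702 higher and 245 lower, so the balance turned round with the scaling.

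**Figure D3:**
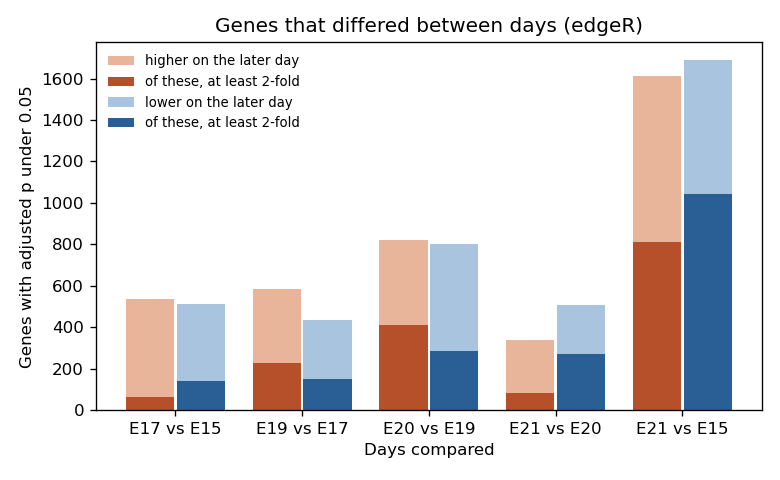
Number of genes that differed between days in edgeR at an adjusted p under 0.05, for each pair of days compared. Pale bars count all genes higher (orange) or lower (blue) on the later day, and dark bars those that differed at least 2-fold. From E19 to E20, 820 genes were higher and 801 lower.

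Over the whole period, from E15 to E21, 198 of the 199 genes of cluster 1 were lower and 271 of the 291 genes of cluster 5 were higher at E21. Cluster 1 dropped by 2.55 and cluster 5 rose by 1.90 on the log2 scale (exact two-sided permutation p = 0.00476 for each, adjusted 0.00915). Of the 20 most abundant genes, 12 fell and 5 rose, with log2 fold changes between -3.98 and 2.40. ENSGALG00000014616.5 rose from 2.57 ± 1.08 normalised CPM at E15 (SD, n = 6) to 2130 ± 810 at E21 (SD, n = 4), a log2 fold change of 9.54 (SE 0.60, adjusted p = 1.89e-14, edgeR with Benjamini-Hochberg). ENSGALG00000017316.4 rose from 3 counts in all E15 libraries to 1271 counts in all E21 libraries. The ratio of their rates was 592, with an exact 95% Poisson interval from 202 to 2880, and the adjusted p was 1.17e-14 in edgeR. Measured from their E15 means, the genes lost after E15 were at least 204-fold (ENSGALG00000042685.1) and at least 114-fold (ENSGALG00000028843.2) lower at E21, with adjusted p-values of 1.04e-06 and 4.18e-06 in edgeR. These folds bound the level at E21 only and leave out the spread between the E15 libraries.

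Between E21 and E15, 3302 of the 5901 genes (56%) differed (edgeR, adjusted p under 0.05), 1612 higher and 1690 lower at E21. At least 2-fold differences were found for 809 of the higher and 1041 of the lower genes. With library totals as the scale, 3414 genes differed, 2102 higher and 1312 lower.

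The authors' deposited table also holds a comparison of samples after against before hatching. Its group means matched the means of the E20 and E21 libraries and of the E15, E17 and E19 libraries for 100% of the genes, within 1% and 0.06 normalised counts. With the mean of the 2 later days set against the mean of the 3 earlier days, each day weighted equally, 3472 genes (58.8%) differed here (edgeR, adjusted p under 0.05), 1724 higher and 1748 lower after hatching. At least 2-fold differences were found for 596 of the higher and 639 of the lower genes. The authors' means are over 9 and 17 libraries, and in a fit of these 2 groups without day 3222 genes differed (edgeR), 1563 higher and 1659 lower. The authors' deposited table, with its stricter thresholds, called 1132 genes (518 higher, 614 lower). Of the 1113 tested, 1100 differed here with each day weighted equally, 1033 of them at least 2-fold. With library totals as the scale, 3704 genes differed, 2612 higher and 1092 lower. The 2 sides differ in age as well as in hatching, and the labels give no samples of 1 age on both sides.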

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

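The values screened for outliers were chosen after the results had been seen. Dixon's test within each day covered 53 sets of library values, and 4 of them held a library whose distance from its nearest neighbour was large against the range of its day. About 1 set in 20 of normally distributed values is singled out in this way by chance, and sets of genes near 0 counts need not follow that rate. The 4 are therefore given as values. The mean relative log2 level of cluster 3 was 0.61 in E15 replicate 6, with 0.91 to 1.08 in the other 5 E15 libraries. The mean relative log2 level of cluster 5 was 1.31 in E21 replicate 3, with 1.12 to 1.16 in the other 3 E21 libraries. ENSGALG00000014616.5 stood at 19.6 normalised CPM in E19 replicate 2 and at 0 to 2.76 in the other 4 E19 libraries. ENSGALG00000028843.2 had its only count of E17 in replicate 3, where it stood at 0.585 normalised CPM. A single count beside libraries without any is always singled out by this rule.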

How the results depend on the processing

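Total-count scaling, the covariate made from the 8 genes that were counted in only 19 of the libraries, the fit of 2 groups without day, the tests of the share of the 20 most abundant genes, the counts per cluster and all values for after against before hatching were chosen after seeing the data. The counts of genes that differed were recomputed in 250 combinations of comparison and setting, and 247 lay within 1.5 times the reported count. The other 3 came from total-count scaling, with 1679 genes for E17 against E15, 1572 for E19 against E17 and 1947 for E21 against E20. That scaling leaves out the TMM factors and moves the median of all genes, which shows the cause. It also took the genes of cluster 4 that fell from E20 to E21 from 84 to 55. In fits of only the 2 days, 1251 genes differed for E20 against E19 and 1301 for E17 against E15, and in limma-voom 1318 and 1334, so the order of these comparisons by count was not kept. In no setting was a gene called in the opposite direction to the reported call. Apart from total-count scaling, the counts ran from 954 to 1334 for E17 against E15, from 855 to 1018 for E19 against E17, from 1251 to 1641 for E20 against E19 and from 652 to 883 for E21 against E20. They ran from 3169 to 4016 for E21 against E15, from 3222 to 4148 for after against before hatching and from 4019 to 5054 for any difference between days. With each library left out in turn, they ran from 751 to 1101, from 874 to 1044, from 1454 to 1631 and from 578 to 897. The lowest were without E15 replicate 4, E19 replicate 1, E20 replicate 5 and E21 replicate 1. For E21 against E15 the 26 fits gave 3025 to 3344 genes, for after against before hatching 3323 to 3474, and for any difference between days 3982 to 4194. The 4 named genes kept their direction and an adjusted p of at most 0.00647 in every setting tried with edgeR, DESeq2 and limma-voom. The filter planned as the stricter one kept 7146 genes, more than the 5901 of the filter used. Of the planned exclusion of abundant genes, the 20 genes with the most counts were left out, and the part on haemoglobin and mitochondrial genes was not run. The W-linked covariate and all gene list tests were not run, for want of gene names. In simulated data with the depths of these libraries and 1 dispersion per gene for all days, 57% to 82% of 2-fold changes were recovered by the quasi-likelihood test of edgeR between 2 days, and at the lowest 53% by limma-voom. The part that depth has in this was not tested, nor was a spread that differs between days.

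With the replicate number as a block (paired by number), 954, 896, 1475, 652 and 3169 genes differed in the 5 comparisons of days in the order given above, with E21 against E15 last, 3401 after against before hatching and 4019 between any days. The numbers did not pair the samples: over 45 pairs of libraries with the same number the correlation of their deviations from the day means lay between -0.115 and 0.0661, and 0 of 26 libraries correlated best with their own number.

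For each comparison, 100 splits of the same libraries into groups of the same sizes were run, the real one included. Only the real one gave as many genes, but not all possible splits were run. A split that mixes days also puts the difference between days into the spread within its groups, which can lower its count. The splits therefore show that the counts followed the day labels, and they do not exclude chance differences between the samples of each day. The real counts in fits of the compared libraries and the highest of the other splits were 1301 and 411 for E17 against E15, 872 and 373 for E19 against E17, 1251 and 1 for E20 against E19, 692 and 131 for E21 against E20, and 3420 and 1 for E21 against E15. They were 3222 and 858 for after against before hatching, and 4195 and 1322 for any difference between days.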

Other observations

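The tests of this part were chosen only after the results they bear on had been seen. The smaller set of clusters in the authors' deposited table, attributed to maSigPro, holds 344 genes, all of which also belong to the clusters attributed to DESeq2. Like those, they were chosen on these libraries and are not independent evidence of direction. In its cluster 2 (109 genes), all but 7 genes rose from E19 to E20, none fell, and 54 rose from E20 to E21. Its mean log2 CPM, relative to the 5 days, was -0.70 ± 0.08 at E19 (SD, n = 5), 1.00 ± 0.20 at E20 (SD, n = 5) and 1.70 ± 0.08 at E21 (SD, n = 4). In its cluster 3, all 48 genes rose from E17 to E19, and 26 of them fell again from E20 to E21. In its cluster 4, all 47 genes fell from E19 to E20 and 41 fell again from E20 to E21 (edgeR, adjusted p under 0.05).

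Genes that changed in successive steps were compared for their direction. From E15 through E17 to E19, 172 genes rose in both steps, where independent lists would share 53, and 96 fell in both against 37.6, while 44 turned. With the E17 libraries split between the steps, 91 rose in both against 20 for independent lists and 33 fell in both against 9.1. From E19 through E20 to E21, 106 rose in both steps against 47.1 and 175 fell in both against 68.8, while 92 turned, and with the E20 libraries split 46 rose in both against 13.7, 28 rose and then fell against 31.5, and 4 fell and then rose against 13.6. From E17 through E19 to E20, 168 genes kept their direction and 198 turned. There, 143 genes rose to E19 and then fell, where independent lists would share 79.1, and 55 fell and then rose, where 60.3 would be shared. Successive steps share the libraries of the middle day, which by chance alone gives the fold changes a correlation of -0.43 around E17, -0.58 around E19 and -0.49 around E20 across genes in simulated unchanged data and no shared calls, against 0.26, -0.03 and 0.12 observed. Around E19 the covariance was -0.0123, against -0.0495 in the simulated data. With odd-numbered E19 libraries in one step and even-numbered ones in the other, 70 genes rose and then fell against 43.3 for independent lists, and 13 fell and then rose against 26.4. In the same split 69 rose in both steps against 39.6, and 60 fell in both against 28.9, and the mean correlation over splits of the E19 libraries was 0.11 with a covariance of 0.0502. In this split, with TMM factors, more genes kept their direction across E19 than turned. The calls without shared libraries were made in that single split only. With library totals as the scale, 1248 of the 1572 genes that differed between E17 and E19 were lower at E19. Of the 2089 that differed between E19 and E20, 1761 were higher at E20. None of the steps was recounted on that scale, so their balance may depend on it.

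The share of counts in the 20 most abundant genes fell by 20.9 points from E19 to E21 (exact two-sided permutation p = 0.00794). A single gene did not account for all of it, but the gene with the most counts held a large part. Without that gene the difference was -12.8 points (exact permutation p = 0.00794). Depth did not account for the fall: among libraries of overlapping depth, between 661931 and 1106816 counts, the lowest share of 4 E19 libraries exceeded the highest of 3 E21 libraries by 19.2 points. Another mixture of cells in the tissue remains open, as does a change within the muscle fibres with age. They cannot be told apart, because 0 of the gene identifiers matched a name that would mark a cell type.

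A set of 8 genes had at most 1 count each in the same 7 libraries and was counted in each of the other 19. It was the most frequent such pattern among 890 genes absent from part of the libraries, with 6 genes in the next. Genes whose low libraries made up whole days had been left out of the 890. So had genes with a median under 4 CPM in the libraries that counted them. The 8 genes together had at most 4 counts in the 7 libraries and at least 56 in the others. Depth did not account for this, since at the lowest level of the 19 libraries, 67.2 CPM, the shallowest of the 7 was due 39 counts. Both kinds of library were found on 4 days. The genes were lacking in 1 of 6 libraries at E15 and 2 of 6 at E17. For the later days the values were 3 of 5 at E19, 1 of 5 at E20 and 0 of 4 at E21. Because patterns of whole days had been left out of the search, this mix is not a test of day. A candidate explanation is the sex of the embryos, with genes of the W chromosome, but the genes have no names here, and the 7 of 26 libraries differ from an equal share with an exact two-sided binomial p = 0.029, so that this stays open along with any other inherited difference.

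The libraries of E19 differed more from each other than those of E15, E17 and E21, with a biological coefficient of variation of 24.8% (n = 5) against 16.6%, 16.9% and 18.2%, and 21.4% at E20. Over the 1477 genes with the most counts, the spread per library was larger at E19 than at E15 (exact two-sided permutation p = 0.00216), at E17 (p = 0.00216) and at E21 (p = 0.0317), with adjusted p-values of 0.00648, 0.00648 and 0.038 over 6 exact tests. The spread of each library was measured from the mean of its own day, which the libraries of that day share. The tests treat these values as independent, so their p-values are approximate. The other 3 exact tests set E20 against the same days, with adjusted p-values of 0.0216 for E15, 0.0228 for E17 and 0.119 for E21, so the larger spread is not particular to E19, and E19 was not tested against E20. Depth did not account for it, since after thinning of every library to 577361 counts the value at E19 still exceeded the highest of the other 3 days by 6.8 points, nor did a single library, since the lowest value with an E19 library left out, 21.8% without replicate 2, exceeded the highest such value of the other 3 days by 2.6 points. Embryos at different points on the way from E17 to E20 may add to it. At most 2.89% of the spread at E19 lay along the straight line between the means of those days with any library left out, against an excess of 41.8% over the highest of the other 3 days. E19 stood off that line on the second principal component, with a mean of -30.7 against -3.9 at E17 and -2.2 at E20. The spread along the ways from E17 to E19 and from E19 to E20 was not measured, so the 2.89% does not bound the part of such embryos. Other differences between the samples or their preparation stay open and untested.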
